A study of Mus musculus with 3 samples.

How the data were processed

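RNA was measured in 3 cultures of mouse keratinocytes, 1 per genotype as the labels give it (wt, ARPC4 ko, Nrf2-EGFP). Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with the TruSeq Stranded mRNA kit and reads were 65 bp, single end. Per the submitters' processing notes, TopHat2 2.1.0, Bowtie 1.1 and HTSeq were used with the mm10 build, and the settings of each tool, including the strand setting of the counting and the annotation release, are not given in the sources used here. The values deposited by the authors are raw counts of reads per gene, 1 table per library with 41214 gene identifiers and no normalisation. Each table also ends with non-gene totals, which were left out of library sizes. They amounted to 9.08% (wt), 8.22% (ARPC4 ko) and 8.48% (Nrf2-EGFP) of all entries, mostly alignments that were not unique (7.64%, 6.81% and 7.13%). Reads of near-identical copies are lost or split by such counting, so values of the Sprr2, glutathione S-transferase, Oas1, Ifit, Krt6 and MHC class I families are uncertain, and Gapdh, with many pseudogenes, had 3.87 CPM in wt. Where the counting ignored strand, overlapping antisense genes could not be told apart.

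Gene symbols and coordinates came from GENCODE M21 on GRCm38 (mm10), matched by gene identifier. A symbol was found for 40254 identifiers, and the rest held 0.127% of the counts. Gene counts were 22924294 in wt, 23033863 in ARPC4 ko and 25723959 in Nrf2-EGFP, in 16823, 16921 and 16780 genes. Mitochondrial genes took 1.33%, 1.41% and 1.56% of the counts, ribosomal protein genes 2.87%, 2.27% and 2.38%, and the 10 most counted genes 5.61%, 4.49% and 5.23%. Libraries were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3 (0.981, 1.06 and 0.966). CPM below are counts divided by these scaled library sizes. Genes with at least 1 CPM in at least 1 library were kept, and 11865 remained. The log2 fold is the log2 ratio of CPM + 0.5, which understates the difference of genes with few counts, whereas folds and ratios are those of the scaled counts without a pseudocount.

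The design has 1 library per group, so the spread between cultures is not measured, no test of genotypes was made and no p-value is given. A gene passed the size rule where its log2 fold was at least 1 in size and the exact 95% interval of the ratio of counts (Clopper-Pearson, conditional on the gene's sum) excluded 1. These intervals compare libraries, not genotypes, and cover counting error only, as reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, or 0.133, 0.123 and 0.121 CPM in wt, ARPC4 ko and Nrf2-EGFP, and folds against 0 are lower bounds set at that floor per library. Each pair of libraries was compared. The groups, the size rule, 31 gene lists, the alternatives and the rule for named genes were chosen before the data were examined.

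The named genes were, for each library against wt, the 10 highest and the 10 lowest log2 folds among genes past the rule with at least 10 CPM in either library, leaving out predicted and unnamed genes. For the overlap they were the 10 same-direction genes with the largest smaller log2 fold and up to 5 opposite ones, and for each list up to 6 members with the largest log2 fold in size. Arpc4 and Nfe2l2 were always named. Some genes that met these rules are not reported here. Other genes, such as Tgm1, Il33, Tslp and those marked in the text, were named after their values were seen. Each list with at least 4 measured members was described by its median log2 fold and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe these libraries and are not tests. Over 27 such lists, 14 medians lay outside the central 95% in ARPC4 ko against wt, 16 in Nrf2-EGFP against wt and 13 between those libraries. For lists of independently drawn genes 1.35 would. Members of a list can move together between any cultures, so 1.35 is not the number to expect without an effect of genotype. Some lists share members. Symbols of Flg and Lce1d were not matched here, and 14 of 47 cornified envelope genes passed the filter. A further 4 lists were chosen after the data were seen.

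Both comparisons with wt share 1 control library. Unchanged libraries, wt included, were therefore simulated 20 times from the mean of the observed libraries, with the simulated wt shared by both comparisons. Noise was Poisson, alone or with assumed biological coefficients of variation of 0.1, 0.2 and 0.4. The steps were tested before use on data for 11865 genes simulated with Poisson noise only, without spread between cultures. In the simulated comparison of ARPC4 ko with wt, the rule found 99 of 100 genes set to differ 3-fold and 100 of 100 set to differ 8-fold. It passed 0 unchanged genes, and the interval covered the true ratio for 94.8% of unchanged genes. With spread between cultures unchanged genes do pass. At an assumed coefficient of variation of 0.2, on average 93.3 passed as higher and 93.75 as lower in ARPC4 ko against wt. In the Poisson comparison of Nrf2-EGFP with wt, a raised list reached percentile 100 and an unchanged list 23.0. Alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a filter of 10 CPM, pseudocounts of 0.1 and 2 CPM, intervals widened by coefficients of variation of 0.2 and 0.4, a stricter 2-fold bound, list means, and medians relative to random lists. Removal of chromosome medians was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.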

Results

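Gene counts from 3 strand-specific RNA sequencing libraries of exponentially growing mouse keratinocytes were compared. Keratinocytes are the epithelial cells of the epidermis, and these were of the C57BL/6 strain and immortalised with SV40. The labels assigned 1 library each to wild type (wt), to a knockout of ARPC4, and to cells expressing a fusion of Nrf2 with the fluorescent protein EGFP. ARPC4 is a subunit of the Arp2/3 complex, which nucleates branched actin filaments. Nrf2, encoded by Nfe2l2, is the transcription factor that drives antioxidant and detoxification genes. The series title asks the design's question: how loss of the Arp2/3 complex relates to Nrf2 activity and to a psoriasis-like state. The libraries held 22924294 (wt), 23033863 (ARPC4 ko) and 25723959 (Nrf2-EGFP) gene counts, and 11865 genes were compared. With 1 library per genotype no difference below has a replicate check, so no p-value is given. Ranges in parentheses are 95% counting intervals, and "passed" means past the 2-fold size rule.

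The targeted genes were examined first. Arpc4 (ENSMUSG00000079426, chromosome 6, 113378115 to 113390448 in mm10) had 94.2 CPM (counts scaled to a common library size) in wt, 61.0 in the library labelled ARPC4 ko and 98.4 in the library labelled Nrf2-EGFP. It was therefore 1.54-fold lower (1.44 to 1.65) in the library labelled ARPC4 ko than in wt, with 1483 counts left, and did not pass the size rule. Between the Nrf2-EGFP and wt libraries its ratio was 1.04 (0.98 to 1.11). The count covers the whole gene, and which part of Arpc4 was deleted is not given in the sources used here, so the remaining counts neither show nor exclude an intact transcript. Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641) had 224.7 CPM in wt, 179.5 in the library labelled ARPC4 ko and 166.4 in the library labelled Nrf2-EGFP. It was 1.35-fold lower (1.30 to 1.41) in the Nrf2-EGFP library and 1.25-fold lower (1.20 to 1.30) in the ARPC4 ko library than in wt. A construct made from another species' sequence, or from coding sequence alone, would be counted to this gene in part or not at all. The title of the Nrf2-EGFP library also holds the word High, whose meaning is not given in the sources used here. Because neither gene matched its label in a simple way, the libraries are named below by their labels only.

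**Figure D1:**
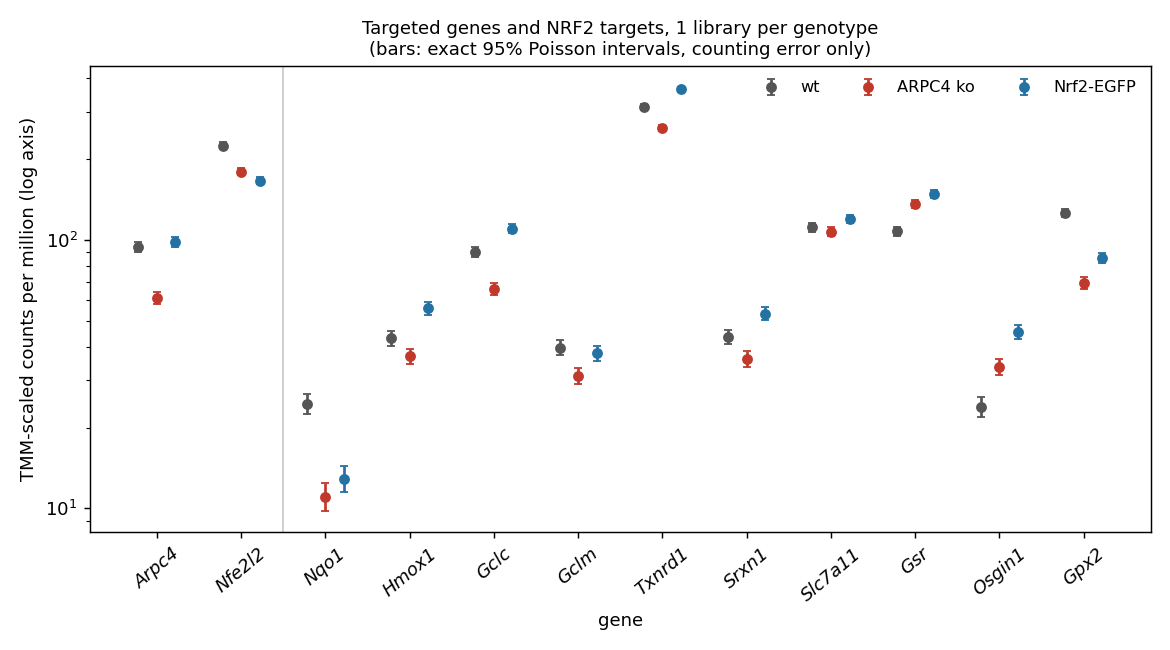
CPM (log axis, TMM-scaled) of Arpc4, Nfe2l2 and 10 NRF2 targets chosen after their values were seen, in the wt (grey), ARPC4 ko (red) and Nrf2-EGFP (blue) libraries, with exact 95% Poisson intervals for counting error only. Arpc4 lay at 61.0 CPM in the ARPC4 ko library against 94.2 in wt, and Nqo1 lay at 24.5 CPM in wt, 11.1 in ARPC4 ko and 12.9 in Nrf2-EGFP.

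In the library labelled ARPC4 ko, most measured cytokine and interferon-stimulated genes were higher than in wt, and most suprabasal differentiation markers were lower. Cxcl5, a neutrophil-attracting chemokine, was 22.4-fold higher (20.3 to 24.7), and Ccl2, a monocyte chemoattractant, was 22.2-fold higher (18.3 to 27.4). Among genes with at least 10 CPM in either library, large positive differences were also in Cp (ceruloplasmin, a copper-binding ferroxidase, 23.7-fold), C1s1 (a complement protease, 25.8-fold, from 9 to 251 counts), Adamts8 (15.6-fold), Ntn1 (netrin 1, 15.5-fold), C3 (the central complement component, 13.1-fold), Mill1 (12.6-fold) and Mmp13 (a collagenase, 11.6-fold). Endou was lower by 86.1-fold (29.1 to 421), with 3 counts left in the ARPC4 ko library. Stc2 (stanniocalcin 2) was 20.2-fold lower (15.5 to 26.9), Spink5 (an epidermal protease inhibitor) 19.5-fold (11.4 to 36.1) and Sprr1b (a cornified envelope protein) 16.6-fold (13.4 to 20.7). Krt6b, Bcat1, Sprr2h, Sprr2k, Adh7 and the noncoding Lncenc1 were between 7.28-fold and 11.8-fold lower. In all, 558 genes passed the size rule as higher and 244 as lower, 6.76% of the genes compared, and 89 and 40 of them differed at least 4-fold. Scaling by total counts alone moved the median of all genes by 0.10 in log2 and the split to 683 higher and 198 lower.

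Among inflammatory cytokines and chemokines, 13 of 19 measured members were higher in the library labelled ARPC4 ko and 1 was lower. The median log2 fold was 1.66, at percentile 100 of random lists matched on expression. Cxcl1 was 7.57-fold higher (7.04 to 8.15), Cxcl2 9.58-fold (7.84 to 11.8), Csf2 10.5-fold (5.81 to 20.8) and Cx3cl1 7.43-fold (5.74 to 9.75). Il33, an epithelial alarmin, was the member lower than in wt, with 8 counts against 37. Psoriasis-associated genes, which share 3 chemokines with that list, had 8 of 22 measured members higher and 2 lower (median 0.61, percentile 100). Without the filter on low counts their median was 0.30. The list fixed 36 genes, and S100a7a, S100a8, S100a9, Defb4, Camp, Il36a, Il36b and Il36g were among those below the filter in every library. Nos2, the inducible nitric oxide synthase, was 34.2-fold higher (11.4 to 168, from 3 counts in wt), and Lcn2, with 0 counts in wt, was at least 12.3-fold higher. Il1rn, the natural antagonist of the interleukin 1 receptor, was 5.19-fold lower (4.05 to 6.74), and the other member lower was Tslp. Of the interferon-stimulated genes, 16 of 24 passed as higher and none as lower, and all 24 had a log2 fold above 0 (median 1.18, percentile 100). Oasl2 was 17.9-fold higher (9.21 to 39.8), Usp18 4.82-fold (3.22 to 7.44), Xaf1 4.27-fold (3.15 to 5.88) and Gbp2 4.29-fold (3.47 to 5.34). With a pseudocount of 2 CPM the median of this list was 0.87, since several members had few counts.

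Suprabasal differentiation markers had 13 of 24 measured members lower and 1 higher in the library labelled ARPC4 ko than in wt, with a median log2 fold of -1.27 (percentile 0). Abca12, a lipid transporter of the skin barrier, was 5.22-fold lower (4.85 to 5.63). Cdsn (corneodesmosin) was 5.62-fold lower (4.42 to 7.23), Dsg1b (a desmosomal cadherin) 27.0-fold (12.8 to 68.2) and Krtdap 13.6-fold (6.67 to 32.5). Tgm1, a transglutaminase that crosslinks the cornified envelope, was the member higher, by 2.30-fold (1.99 to 2.67). Of 14 measured cornified envelope proteins, 7 were lower and none higher (median -1.10, percentile 0), with Sprr1a 3.01-fold (2.32 to 3.94) lower. Without the filter on low counts that median was -0.44. All 4 stress keratins, which are induced in wounded and hyperproliferative epidermis, were lower (median -1.78, percentile 0). They are not in the list of psoriasis-associated genes, whose median was 0.61, so that median does not reflect them. Krt6a was 2.63-fold lower (2.59 to 2.67), from 2930 to 1113 CPM, Krt16 4.56-fold (4.24 to 4.91) and Krt17 2.06-fold (2.03 to 2.08). The list of NRF2-responsive epidermal genes, which includes those 3 keratins, had 4 of 7 members lower and 1 higher (median -1.04, percentile 0), the higher one being Slpi, a protease inhibitor, by 3.60-fold (3.12 to 4.17). Among 14 basal keratinocyte markers, Krt5 (2.11-fold) and Krt14 (2.27-fold) were lower, and the median of the list was -0.18 (percentile 36.6).

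The 34 measured NRF2 targets did not stand apart from matched lists in the library labelled ARPC4 ko. Their median log2 fold against wt was -0.15 (percentile 7.45), 10 of them lay above 0, and 2 passed as higher and 1 as lower. Nqo1, a quinone reductase often used as a readout of Nrf2, was 2.21-fold lower (1.91 to 2.57). Gstm1 was 2.41-fold higher (1.82 to 3.22) and Aldh3a1 13.9-fold higher (5.15 to 52.6), the latter from 4 counts in wt. Of 13 glutathione S-transferases 1 was higher and 1 lower (median 0.24, percentile 88.0), and at a filter of 10 CPM that median was -0.04. None of 11 NRF2 pathway regulators passed (median 0.08). Sqstm1, the autophagy receptor that competes for the NRF2 repressor Keap1, was 1.88-fold lower (1.81 to 1.95). None of the 10 Arp2/3 subunits passed, and their median was -0.26 (percentile 5.93), with Arpc4 the lowest. Of 24 regulators of the complex, Wipf1 was the only one past the rule, 4.78-fold higher (3.71 to 6.21). Of 14 formins and other actin nucleators it was Fhod3, with 27 counts in wt and 73 in ARPC4 ko.

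The medians of 3 stress and metabolic lists lay below the central 95% of random lists in the library labelled ARPC4 ko against wt, although most of their members did not pass the size rule. The integrated stress response, the ATF4-driven program of amino acid shortage and unfolded proteins, had 10 of 26 members lower, none higher and none with a log2 fold above 0 (median -0.86, percentile 0). Trib3 was 3.88-fold lower (3.65 to 4.11), Ddit3 3.03-fold (2.72 to 3.38), Vldlr 3.61-fold (3.19 to 4.10) and Aldh1l2 2.87-fold (2.72 to 3.04). Cholesterol synthesis genes had 3 of 23 members lower (median -0.49, percentile 0), namely Idi1 (2.28-fold), Hmgcs1 (2.04-fold) and Lss (2.05-fold). Glycolysis genes had 2 of 21 lower and 1 higher (median -0.52, percentile 0). Ldha, the lactate dehydrogenase subunit, was 1.88-fold lower (1.84 to 1.92) without passing. Basement membrane and matrix genes had 6 of 26 higher and 1 lower (median 0.52, percentile 100). Among them Mmp3 (stromelysin 1) was 45.3-fold higher (15.2 to 222, from 3 counts in wt), Fbn1 (fibrillin 1) 4.69-fold (3.97 to 5.58) and Ltbp1 2.76-fold (2.63 to 2.91). Medians above the central 95% of random lists were also measured for YAP and TEAD targets (0.21, 1 of 18 higher and 2 lower), focal adhesion and integrin genes (0.25, 1 of 25 higher) and hair follicle and sebaceous markers (0.76, 1 of 6 higher). The hair follicle list fixed 18 genes, and its keratins, Lgr5, Lgr6 and Pparg were among those below the filter. The bootstrap interval of its median, -0.11 to 1.14, included 0. Cell cycle genes had none of 34 past the rule (median -0.13, percentile 24.1). The medians of p53 targets (-0.09, mean 0.03), SRF and MRTF targets (-0.09), cell-cell junctions (-0.05) and the EGF family (0.11) lay within the central 95%, and with scaling by total counts the first 3 of these were above 0.

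**Figure D2:**
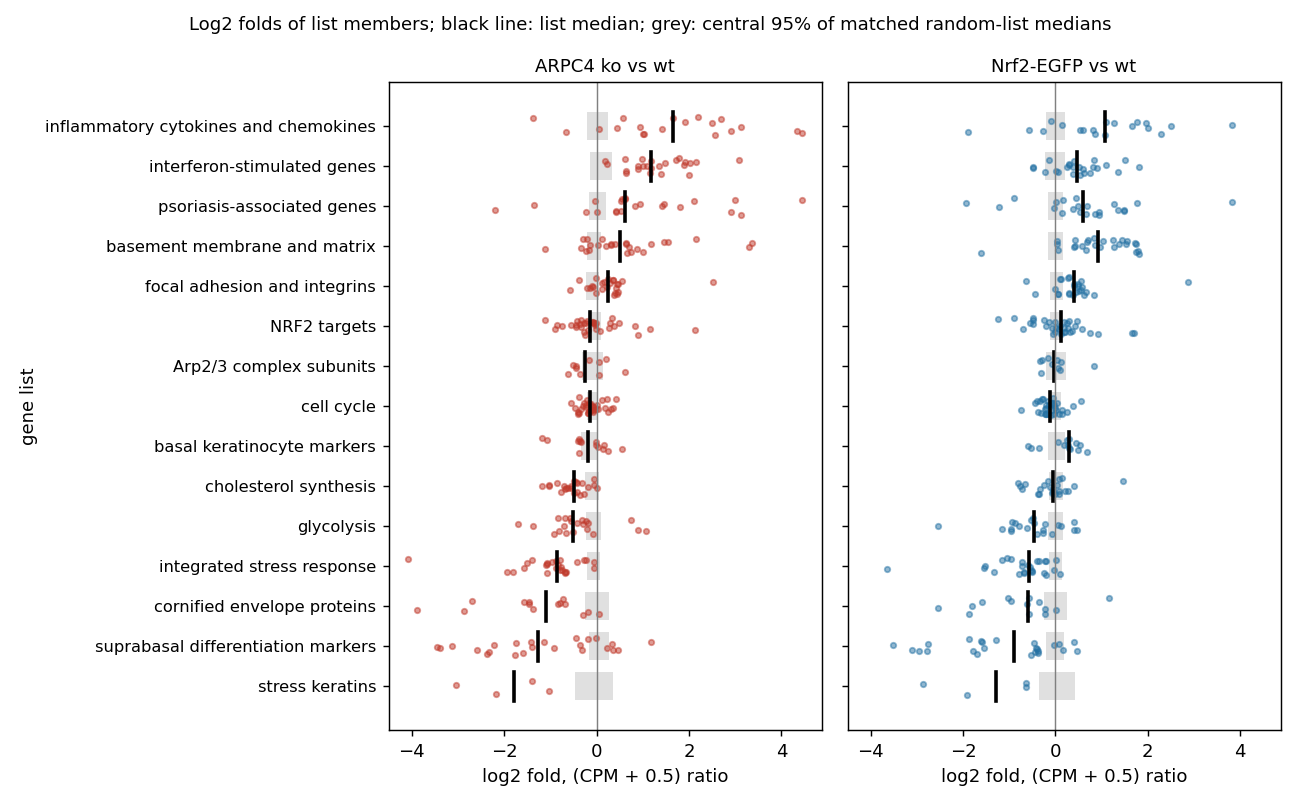
Log2 fold of (CPM + 0.5) against wt for each measured member of 15 gene lists fixed before the data were examined, in the ARPC4 ko library (left, red) and the Nrf2-EGFP library (right, blue). Black lines mark list medians and grey bars the central 95% of medians of 10000 random lists. Cytokine medians lay at 1.66 and 1.07 and stress keratin medians at -1.78 and -1.28, while NRF2 target medians lay at -0.15 and 0.11.

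In the library labelled Nrf2-EGFP, NRF2 targets as a group lay close to wt, and the larger differences were in matrix, cytokine and differentiation genes. The median log2 fold of the 34 NRF2 targets was 0.11 (percentile 95.1, within the central 95% of random lists), with 20 members above 0, 2 passing as higher and 1 as lower. Gsta4 was 3.40-fold higher (2.88 to 4.04), Aldh3a1 9.28-fold higher (3.36 to 35.7, from 4 counts in wt) and Mgst1 3.07-fold lower (1.88 to 5.19). Nqo1 was 1.89-fold lower (1.65 to 2.18) and Osgin1 1.91-fold higher (1.72 to 2.12), and neither passed. Of targets chosen after their values were seen, Gclc was 1.22-fold higher (1.15 to 1.29), Hmox1 1.29-fold (1.19 to 1.40), Txnrd1 1.16-fold (1.13 to 1.20), Srxn1 1.22-fold (1.12 to 1.33), Gsr 1.38-fold (1.31 to 1.45) and Slc7a11 1.07-fold (1.02 to 1.13). Gpx2 was 1.46-fold lower (1.38 to 1.55) and Gclm 1.05-fold lower, with an interval that includes 1. None of the NRF2 pathway regulators passed (median 0.14), and glutathione S-transferases had 1 of 13 higher and 2 lower (median -0.14), the lower ones being Mgst1 and Mgst2. NRF2-responsive epidermal genes had 3 of 7 lower and 1 higher (median -0.64, percentile 0), with Slpi 2.63-fold higher (2.27 to 3.06) and Krt16 3.82-fold lower (3.57 to 4.09).

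Among genes past the rule with at least 10 CPM in either library, ranked by log2 fold, the highest in the library labelled Nrf2-EGFP against wt included Pitx1 (a homeobox transcription factor), 21.1-fold higher (12.4 to 39.0), Adamts8 (15.5-fold), Vegfc (the lymphangiogenic growth factor, 15.3-fold), Cxcl5 (14.4-fold), Ccbe1 (a secreted factor needed for VEGF-C processing, 13.0-fold), Gfra2 (11.6-fold), Ntn1 (10.3-fold), Msln (mesothelin, 10.2-fold), Tns1 (7.91-fold) and C3 (6.62-fold). By the same ranking, the lowest included Spink5, 21.4-fold lower (12.3 to 40.8), Stc2 (14.2-fold), Zfp750 (a transcription factor of epidermal differentiation, 12.0-fold), Krt6b (9.77-fold), Cdsn (8.06-fold), Bnip3 (6.52-fold), Adh7 (6.42-fold), Sprr1b (6.04-fold), Vcan (the proteoglycan versican, 5.43-fold) and Asprv1 (an epidermal protease, 5.33-fold). In all, 423 genes passed as higher and 243 as lower, 5.61% of those compared, and 58 and 37 differed at least 4-fold.

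Basement membrane and matrix genes had 12 of 26 members higher in the library labelled Nrf2-EGFP and 1 lower (median 0.91, percentile 100), the lower one being Nid1, with 23 counts in wt and 0 in Nrf2-EGFP. Tnc (tenascin C) was 3.52-fold higher (3.42 to 3.63), Sparc 3.94-fold (2.78 to 5.70) and Ltbp1 3.35-fold (3.19 to 3.52). Suprabasal markers had 12 of 24 lower and none higher (median -0.90), cornified envelope proteins 5 of 14 lower and 1 higher (median -0.59), and stress keratins 2 of 4 lower (median -1.28), all 3 at percentile 0. Cytokines and chemokines had 10 of 19 higher and 1 lower (median 1.07), psoriasis-associated genes 6 of 22 higher and 2 lower (median 0.60) and interferon-stimulated genes 4 of 24 higher and none lower (median 0.46), all 3 at percentile 100. Without the filter on low counts the psoriasis median was 0.15, and with a pseudocount of 2 CPM the interferon median was 0.20. Csf2 was 6.79-fold higher (3.70 to 13.6), Ccl2 6.17-fold (5.01 to 7.66) and Oasl2 6.64-fold (3.29 to 15.2). The integrated stress response had 6 of 26 lower (median -0.57, percentile 0), with Trib3 2.53-fold lower (2.40 to 2.66) and Ddit3 2.93-fold (2.64 to 3.26), and glycolysis had 2 of 21 lower (median -0.46, percentile 0). Cholesterol synthesis did not stand apart (median -0.06, percentile 14.2).

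Further lists were compared between the library labelled Nrf2-EGFP and wt. Basal keratinocyte markers had none of 14 past the rule but a median of 0.29 (percentile 99.8), with Krt5 1.44-fold lower (1.43 to 1.45). YAP and TEAD targets had 2 of 18 higher (median 0.44, percentile 100), namely Ccn2, 3.97-fold (3.58 to 4.41), and Ccn1, 2.80-fold (2.67 to 2.94). Focal adhesion and integrin genes had 1 of 25 higher (median 0.40, percentile 100). Cell cycle genes had a median of -0.12 (percentile 0.54) and p53 targets one of -0.18 (percentile 1.71), with none of 34 and 2 of 21 members lower by the rule. Arp2/3 subunits (-0.02), regulators of the complex (-0.03, mean 0.09), formins (0.07), SRF and MRTF targets (0.05), cell-cell junctions (0.01), the EGF family (0.21) and hair follicle markers (0.32) lay within the central 95%. Junctions turned to -0.02 with scaling by total counts. Fibroblast and mesenchymal markers had 4 of 8 measured members higher in Nrf2-EGFP (median 1.02, above the central 95%) and 2 of 8 in ARPC4 ko (median 0.48, percentile 93.5). The mesenchymal cadherin Cdh2 was 4.16-fold higher (3.77 to 4.60) in Nrf2-EGFP, whereas Vim, with few counts, was the lowest member there, with a log2 fold of -0.74. The list fixed 22 genes, and the collagens Col1a1, Col1a2 and Col3a1 were among those below the filter. Few markers of other cell types passed the filter, with 1 of 16 immune markers (Cd68), 1 of 8 melanocyte markers (Mitf) and 3 of 8 endothelial markers (Eng, Flt1, Pecam1) above it, of which Flt1 was 2.09-fold higher in ARPC4 ko and 2.42-fold higher in Nrf2-EGFP than in wt. Of simple epithelial keratins Krt8 and Krt18 were measured, and neither passed.

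The differences of both libraries from wt overlapped. Higher than wt in both were 251 genes, against 19.9 for independent lists of these sizes, and lower in both were 133, against 5.0. Across genes, which are not independent replicates, the log2 folds had a Pearson r of 0.730 and a Spearman rho of 0.699. Independence is not the value without change, because both share the wt library. Unchanged libraries simulated with counting noise, sharing a simulated wt library, gave an r of 0.524 and no gene in the overlap. With an assumed biological coefficient of variation of 0.2 they shared 16.25 higher and 5.75 lower genes, and with 0.4 they shared 515 and 346, but from longer lists than observed, with 1286 and 1282 genes higher and 1267 and 1260 lower. The simulated r at 0.4 was 0.501, with a highest value of 0.512, and 23.8 genes on average passed in opposite directions. The covariance was 0.2001 against 0.00757 simulated, a difference of 0.193. At those coefficients of variation the simulated covariance was 0.0853 and 0.334, the latter above the observed value. The wt library is 1 library and cannot be split, so part or all of the excess may come from the shared control. Of the pairs of libraries, ARPC4 ko and Nrf2-EGFP were the most alike, with a Pearson r of log2 (CPM + 0.5) of 0.986. With wt it was 0.971 for ARPC4 ko and 0.976 for Nrf2-EGFP. The same-direction genes with the largest smaller fold were Cxcl5, Adamts8, Ntn1, Vegfc and C1s1 (higher) and Stc2, Spink5, Dsg1b, Krt6b and Dsg1a (lower). Passing in opposite directions were 2 genes, Tfap2b and Cldn6.

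**Figure D3:**
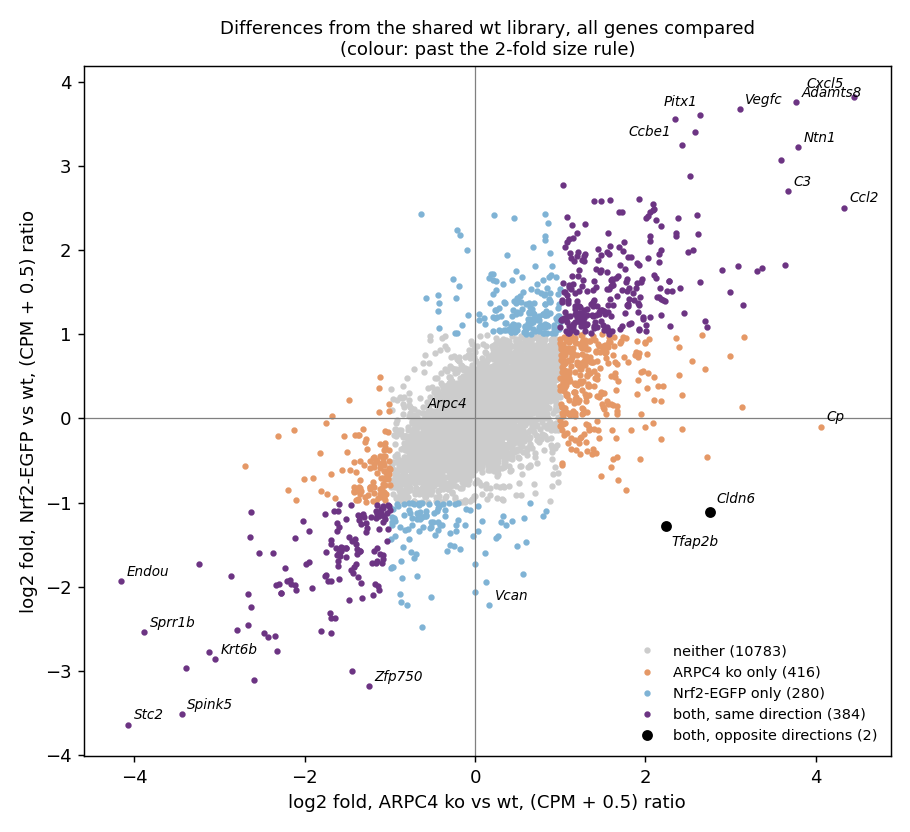
Log2 fold of (CPM + 0.5) against the shared wt library for 11865 genes, ARPC4 ko on the horizontal and Nrf2-EGFP on the vertical axis, coloured by the size rule. Genes past the rule in both in the same direction number 384, and 2 pass in opposite directions.

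Compared directly, without the wt library, the library labelled ARPC4 ko had 239 genes higher and 114 lower than the library labelled Nrf2-EGFP, 2.98% of those compared. Interferon-stimulated genes were higher in 10 of 24 members and lower in none, with all 24 above 0 (median 0.82, percentile 100), and at a filter of 10 CPM the median was 0.41. Usp18 was 3.67-fold higher (2.60 to 5.30) and Xaf1 2.34-fold (1.85 to 2.97). Cytokines were higher in 5 of 19 (median 0.51, percentile 100), among them Cxcl2, 8.63-fold (7.19 to 10.4), and Cx3cl1, 4.67-fold (3.81 to 5.76). NRF2 targets had a median of -0.22 between ARPC4 ko and Nrf2-EGFP (percentile 0.02), with 7 of 34 above 0, but none passed as lower and 2 passed as higher (Gstm1 and Mgst1). With scaling by total counts that median was -0.10. Glutathione S-transferases had 2 of 13 higher and none lower (median 0.23, within the central 95%), but a median of -0.30 at a filter of 10 CPM. Matrix genes (-0.39, 2 of 26 higher and 2 lower), basal markers (-0.39, none of 14 past the rule), cornified envelope proteins (-0.43, 3 of 14 lower), the integrated stress response (-0.30, 1 of 26 lower), cholesterol synthesis (-0.38, 1 of 23 lower), YAP and TEAD targets (-0.20, 1 of 18 lower) and fibroblast markers (-0.34, 1 of 8 higher and 2 lower) had medians below the central 95%. p53 targets (0.13, 3 of 21 higher), hair follicle markers (0.54, none of 6) and cell cycle genes (-0.03 against a random-list median of -0.11, none of 34) had medians above it. The cell cycle median was 0.09 with scaling by total counts. Suprabasal markers had none of 24 past the rule (median 0.05, or -0.05 with genes at 0 counts set at their bound). Scaling by total counts moved the median of all genes by 0.13, and the share of higher among passing genes, 67.7%, was 45.6% at a filter of 10 CPM and 54.4% with a pseudocount of 2 CPM.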

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

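Tests of label swaps, of the segment around Arpc4, of its remaining counts, of transgene counting and of chromosome-wide shifts were chosen after the results were seen, and those of counting noise, of the wt library and of scaling before.

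Tfap2b and Cldn6 drew attention because they differed from wt in opposite directions in the libraries labelled ARPC4 ko and Nrf2-EGFP. Tfap2b, an AP-2 transcription factor (chromosome 1), had 16 counts in wt, 127 in ARPC4 ko and 0 in Nrf2-EGFP, so it was at least 43.3-fold higher in ARPC4 ko than in Nrf2-EGFP. Cldn6, a claudin of tight junctions (chromosome 17), had 17, 194 and 2 counts, a log2 fold of 3.87 between ARPC4 ko and Nrf2-EGFP. The difference between the genotypes was not tested, since each has 1 library. With a pseudocount of 2 CPM the log2 folds of Tfap2b and Cldn6 between Nrf2-EGFP and wt were -0.44 and -0.41, short of the size rule.

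Arpc4 was counted at a reduced level, not near 0, in the library labelled ARPC4 ko. An exchange of the ARPC4 ko and wt labels would leave the library labelled ARPC4 ko no lower than the third library, and its Arpc4 ratio to Nrf2-EGFP was 0.620 (0.581 to 0.662). That range covers counting error only, and the spread of Arpc4 between cultures is not measured, so an exchange is not excluded. Fewer copies of the surrounding segment would lower its neighbours too, but the median log2 fold of 23 measured genes within 1 Mb was 0.25 (0.09 to 0.28). The remaining 1483 counts may come from transcripts of a recombined allele or from cells that kept the gene, and counts per gene cannot tell these apart because they are not resolved by exon. A lower Arpc4 transcript level in a true knockout stays open with both.

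Both libraries differed from wt in shared genes. Counting noise of the wt library would leave the covariance of log2 folds within the simulated range, and the observed 0.2001 exceeded the highest of 20 simulations, 0.00806. Chromosome-wide shifts would bring the correlation down to the simulated one, and it was 0.721 with chromosome medians removed, against a highest simulated 0.549. A wt culture that itself differed from other wt cultures may account for part or all of it. With 1 wt library this and a shared effect of both genotypes cannot be told apart. Unchanged libraries with an assumed coefficient of variation of 0.4 in each gave a covariance of 0.334, above the observed one. Their r was lower, 0.501 against 0.730, with 1286 genes higher in ARPC4 ko against 558, so that setting does not resemble these libraries. It gave every library the same spread, so a wt culture that alone differed was not simulated and these values do not bear on it.

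NRF2 targets as a group lay near the wt level in the library labelled Nrf2-EGFP. Whether scaling hides a general rise stays open, because the 3 scalings tried, with a highest median log2 fold of 0.12, moved all genes too little to test it. An exchange of the ARPC4 ko and Nrf2-EGFP labels would need lower Arpc4 in Nrf2-EGFP, against the same ratio of 0.620. The range of that ratio covers counting error only. An exchange of the wt and Nrf2-EGFP labels was not tested. Arpc4, with a ratio of 1.04 (0.98 to 1.11) between Nrf2-EGFP and wt, cannot test it. The transgene may not be counted to Nfe2l2, whose ratio to wt was 0.741 (0.711 to 0.772), and this value decides nothing about its level. A wt culture with active Nrf2, or an Nrf2-EGFP protein of little activity under these growth conditions, was not tested.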

How the results depend on the processing

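Removal of chromosome medians was chosen after the data were seen, and the other alternatives before. The direction of 43 list medians outside the random range was recomputed over 385 alternatives, and 3 reversed. These were all the cell cycle median between ARPC4 ko and Nrf2-EGFP, at 0.0937 with total counts, 0.000722 as a mean and 0.0793 relative to random lists, against -0.03. Of the list medians recomputed over all alternatives, 693 values stayed within the bootstrap interval of their list and 30 moved. For 56 folds of named genes, a fold past the size rule was taken to stay where it still passed in the same direction, whatever its size. A fold not past the rule was taken to stay within its counting interval. Of the recomputed values of these folds 271 stayed so and 7 moved, and 2 fell short of the size rule. The Arpc4 log2 fold between Nrf2-EGFP and wt, 0.06, changed sign to -0.000624 with chromosome medians removed.

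Counts of genes past the rule depended on the treatment of low counts (filter, pseudocount) and on the fold and spread demanded (coefficient of variation, near bound). In ARPC4 ko against wt, higher and lower genes rose from 558 and 244 to 584 and 254 without a filter. With a pseudocount of 0.1 CPM they were 688 and 299. The settings that follow lowered the counts, and by construction keep fewer genes or demand more. At a filter of 10 CPM, a pseudocount of 2 CPM and a coefficient of variation of 0.4, higher and lower genes were 253 and 121, 311 and 143, and 146 and 56 in ARPC4 ko against wt. They were 242 and 92, 258 and 104, and 106 and 53 in Nrf2-EGFP against wt, and 52 and 62, 80 and 67, and 41 and 18 in ARPC4 ko against Nrf2-EGFP. With the near bound of the interval at least 2-fold, higher genes were 357, 281 and 142 in these comparisons, and lower genes 71 in the last. Genes higher in both against wt were 150 (10 CPM) and 146 (pseudocount 2), and lower in both 58 and 64.

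The correlation of 0.730 was 0.710 without a filter, 0.784 at 10 CPM, 0.750 and 0.717 with pseudocounts of 2 and 0.1, and 0.721 with chromosome medians removed, and the cause was not tested. The Arpc4 log2 fold between ARPC4 ko and wt, -0.62, was -0.52 with total counts and -0.79 with chromosome medians removed. No paired analysis was possible because each genotype has 1 library, and for the same reason none could be left out. Depth limits genes near the floor, where 1 count is worth 0.0445 CPM in wt.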

Other observations

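All gene lists in this part were chosen after the data were seen. Complement components had 3 of 6 measured members higher in the library labelled ARPC4 ko than in wt and the same number in Nrf2-EGFP, in a list made because C3 and C1s1 had large folds. The initiating protease C1s1 was 25.8-fold higher (13.4 to 57.1) in ARPC4 ko and 17.7-fold (9.11 to 39.3) in Nrf2-EGFP than in wt, and its partner C1ra had 8 counts in wt, 95 in ARPC4 ko and 83 in Nrf2-EGFP. The MHC class I antigen presentation list had 8 of 18 members higher in ARPC4 ko and none lower (median 0.93), against 2 of 18 in Nrf2-EGFP (median 0.31). Compared directly, 3 of 18 were higher in ARPC4 ko than in Nrf2-EGFP (median 0.51). Tapbp, the peptide-loading chaperone tapasin, was 2.71-fold higher (2.59 to 2.84) in ARPC4 ko, and Psmb8, an immunoproteasome subunit, 5.81-fold (3.99 to 8.72).

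Hypoxia-inducible factor targets had 2 of 19 members lower in ARPC4 ko (median -0.52) and 3 of 19 in Nrf2-EGFP (median -0.48), none higher. This list shares members with the glycolysis list, Bnip3 among them, so their medians are not separate results. Ak4, an adenylate kinase, was 5.14-fold (4.31 to 6.18) and 4.45-fold (3.77 to 5.28) lower, and Bnip3, a mitophagy receptor, 3.40-fold (2.85 to 4.06) and 6.52-fold (5.21 to 8.25). The peptidylarginine deiminases Padi3 and Padi4, 2 of 4 measured, separated the libraries. Padi3 had 173 CPM in wt, 53.8 in ARPC4 ko and 177 in Nrf2-EGFP, and was 3.28-fold lower (3.09 to 3.49) in ARPC4 ko than in Nrf2-EGFP. Padi4 was 2.49-fold lower (2.33 to 2.66) in that comparison. Vim, the mesenchymal intermediate filament gene, had 12 counts in wt, 68 in ARPC4 ko and 3 in Nrf2-EGFP, whereas Twist1 had 6, 13 and 47.

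Median log2 folds per chromosome ranged from -0.20 to 0.29 in ARPC4 ko against wt, with bootstrap intervals excluding 0 for 16 of 20 chromosomes. They ranged from -0.31 to 0.19 in Nrf2-EGFP against wt, for 18 of 20, and from -0.16 to 0.11 between ARPC4 ko and Nrf2-EGFP. Chromosome 17 had medians of 0.29 and 0.17, chromosome 5 of 0.20 and 0.19, chromosome 3 of -0.20 and -0.31, and chromosome 12 of -0.17 and -0.29, in ARPC4 ko and Nrf2-EGFP against wt. Random lists were matched on expression and not on chromosome. Medians of lists with several members on the same chromosome may therefore include its shift. The cornified envelope genes Sprr1b, Sprr2h and Sprr2k, for example, lie on chromosome 3. Across genes, log2 folds had a Spearman rho with GC content of 0.185 and 0.154 in ARPC4 ko and Nrf2-EGFP against wt. Between ARPC4 ko and Nrf2-EGFP it was 0.0625. With the length of the longest transcript, rho was 0.111, 0.138 and -0.0271 in the same order. Xist, the X inactivation transcript, had 1021, 1247 and 1134 CPM in wt, ARPC4 ko and Nrf2-EGFP, and 4 Y-linked genes (Ddx3y, Uty, Kdm5d, Eif2s3y) together had 0, 3 and 0 counts.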
